A study of Mus musculus with 6 samples.

How the data were processed

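The series profiled RNA from brain hemisphere middle sections of 6 mice by RiboTag immunoprecipitation and sequencing. RiboTag is a mouse allele that puts an epitope tag on the ribosomal protein Rpl22 in cells with Cre recombinase, so that tagged ribosomes and the RNA on them can be pulled down. The series title names the astrocyte transcriptome, while the labels used here give no Cre driver. Per the labels, 3 animals had the middle cerebral artery occluded for 1 h (MCAO) and 3 control animals had no occlusion; no sham operation is described. Animals were killed after 3 days. The left hemisphere was used in both groups. The RNA was precipitated 2 times per animal and pooled, extracted with TRIZOL, and polyA RNA was made into Illumina TruSeq libraries. The series design names 2 technical replicates per animal, which are 1 column per animal in the deposited table; how they were joined is not given in the sources used here. Each library is therefore 1 animal. Replicate numbers follow the order of the records and only name a library. Input RNA of the same tissue was not used here.

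The deposited table holds 12968 genes by 6 libraries in a normalised signal, which the values show to be read counts per gene divided by 1 scale factor per library. The submitters' processing notes list the genome build mm10 and the tools CASAVA 1.8, HISAT2, Partek 6.6, R 3.3.1 and DESeq2, with no role or order; the counting step, strand setting, gene filter and scale factors are not given in the sources used here. Apart from the lowest values, each column is made of whole multiples of its own step, from 0.288 in control 1 to 3.11 in MCAO 2. Division by that step gave whole reads, to within 0.1 read, for 99.95% of the values of control 1 and all values of the other 5 libraries. Values under 1 stand at exactly 1 in the deposited table, so 0 reads are listed as 1, and in control 1, the deepest library, as many as 3 reads are hidden there. This floor hides the step from a reading of the lowest values alone, and only the column of MCAO 2 passed that stricter reading. No gene of the table has a largest value under 10.6, so genes with few reads in every library are not analysed here. The values are called scaled read counts below.

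Recovered reads in the deposited genes numbered 9519548 in control 1, 1538901 in control 2, 1816934 in control 3, 4567615 in MCAO 1, 882263 in MCAO 2 and 4027185 in MCAO 3. The limit that a count of 0 allows, 3 reads per library, equals 0.863, 5.32, 4.53, 1.76, 9.33 and 2.00 scaled reads in the same order, and 3.57 as the mean over the controls. Intervals and floors cover counting error only, since PCR copies are not independent molecules. No pair of libraries had identical values, and none was counted as a repeat of another.

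Differential expression was tested with limma 3.58.1 in R 4.3.3 (linear model, empirical Bayes with an intensity trend, two-sided) on log2(scaled read count + 1), over the 12549 genes with a mean of at least 10 over the 6 libraries. The p-values were adjusted by Benjamini-Hochberg, and a gene is called at an adjusted p under 0.05. Log2 changes are MCAO over control on the log2(value + 1) scale, which understates the change of low genes. SE is the moderated standard error. Where every control stands at the floor, the fold of the MCAO mean is given as a lower bound against the mean floor of the controls. This bound leaves out the spread among the MCAO animals. Among genes with some controls at the floor, C3ar1, Hspb1, Spi1 and Top2a have 1 such control and Cdk1 and Timp1 have 2, and their log2 changes depend on the floor value. The labels give no batch, pairing or sex, and the model has none.

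There were 27 gene lists, 16 of processes and 11 of cell type markers, written from general knowledge. They were tested with limma's camera (preset correlation 0.01, against all other genes tested, Benjamini-Hochberg over the 26 lists with a measured gene), by camera with an estimated correlation, and by fry. A listed gene is called measured if it passed the filter on the mean. That mean covers both groups, so a gene low in controls could pass through its MCAO values. Counts of risen or fallen members are of measured genes only. With the preset correlation 17 lists were called, 15 by fry, and 0 with an estimated correlation, where 11 were at an unadjusted p under 0.05. Named genes follow a rule: the 6 largest changes in each direction among called genes whose groups do not overlap and whose mean is in the upper 50% of tested genes, passing over gene models without a symbol; 2 members of each list, the most changed called members or else the most abundant; and 12 genes named in any case, Rpl22 among them. The rule gave 66 genes, some of which are not reported here. Genes outside it are said to have been chosen after their values were seen. A score for A2 against A1 reactive genes is the difference of the mean log2 values of the lists in each library, tested by a two-sided exact permutation test, whose smallest possible p with 3 against 3 animals is 0.1.

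The grouping, test, filter, thresholds, lists, named-gene rule and most alternatives were fixed before the data were examined. The alternatives fixed then were other pseudocounts (0.1 and 5), no filter, a mean of 50, median ratio scaling, quantile normalisation, no intensity trend, robust moderation, no moderation, edgeR 4.0.16 on the recovered reads, an adjusted p under 0.01, each library left out in turn, camera with an estimated correlation and on ranks, process lists without members of marker lists, and components of the 500 most variable genes. The edgeR quasi-likelihood test used trimmed mean scaling and counted floored values as 0 reads. It called 520 genes. Alternatives chosen after seeing the data were library weights, leaving out the 2 shallowest libraries, removal of a lowess trend on gene span from each library (span fraction 0.3), and leaving out lists with fewer than 3 measured genes, with and without an estimated correlation. Gene lists added after seeing the data appear among the closing observations, and the striatal projection neuron list also beside the cholesterol synthesis genes.

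The scripts were tested on simulated counts for the 12549 genes, with 200 genes changed. Counts were drawn from the means and depths of these libraries and from edgeR's trend of dispersion on abundance. Each simulated gene followed that trend exactly, with no dispersion of its own. Such data favour moderation, so the recovered shares and false calls with it may look better than for real genes. limma recovered 14%, 56%, 84% and 100% of genes changed 1.5-, 2-, 4- and 8-fold, with 3 false calls, and edgeR 14%, 60%, 90% and 100%, with 5. Without moderation, 0%, 0%, 4% and 4% were recovered. Of 25 simulated lists, camera called the shifted list and 0 unshifted ones, with the preset and with the estimated correlation. Simulated genes were drawn independently of each other, while the estimated correlation of the real astrocyte transport list was 0.82. The simulation therefore could not show false list calls that arise from correlated genes under the preset correlation. Gene coordinates are 1-based on GRCm38.p6, the assembly that mm10 names, from a gene table in which 12743 of the 12968 symbols (98.3%) were found. Reads of gene families with near-identical members can be split between them: alpha globins, gamma protocadherins, which share constant exons, and ribosomal protein genes, which have pseudogenes, are uncertain in that way. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.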

Results

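Ribosome-bound RNA of the left hemisphere was compared between 3 mice killed 3 days after a 1 h occlusion of the middle cerebral artery (MCAO) and 3 control mice without occlusion. The series title frames the comparison as a search for stroke targets in the astrocyte transcriptome. Depth ranged from 882263 reads in MCAO 2 to 9519548 in control 1. The first principal component held 42.4% of the variance and parted the groups, with scores of -40.7 to -22.9 in controls and 19.5 to 48.0 after MCAO. The second component held 19.6% and set control 2 and MCAO 2, the shallowest library of each group, apart from the rest, at -22.7 and -33.6, while control 3, nearly as shallow as control 2, lay at 6.87. Pearson correlations across genes, which are not independent replicates, were 0.934 to 0.966 within groups and 0.890 to 0.943 between them. Rpl22, the gene that the RiboTag allele tags, stood at 197 ± 32.8 scaled reads in controls and 251 ± 52.1 after MCAO (SD, n = 3 each), a log2 change of 0.35 (SE 0.19) that did not pass the test (limma adjusted p = 0.330).

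**Figure D1:**
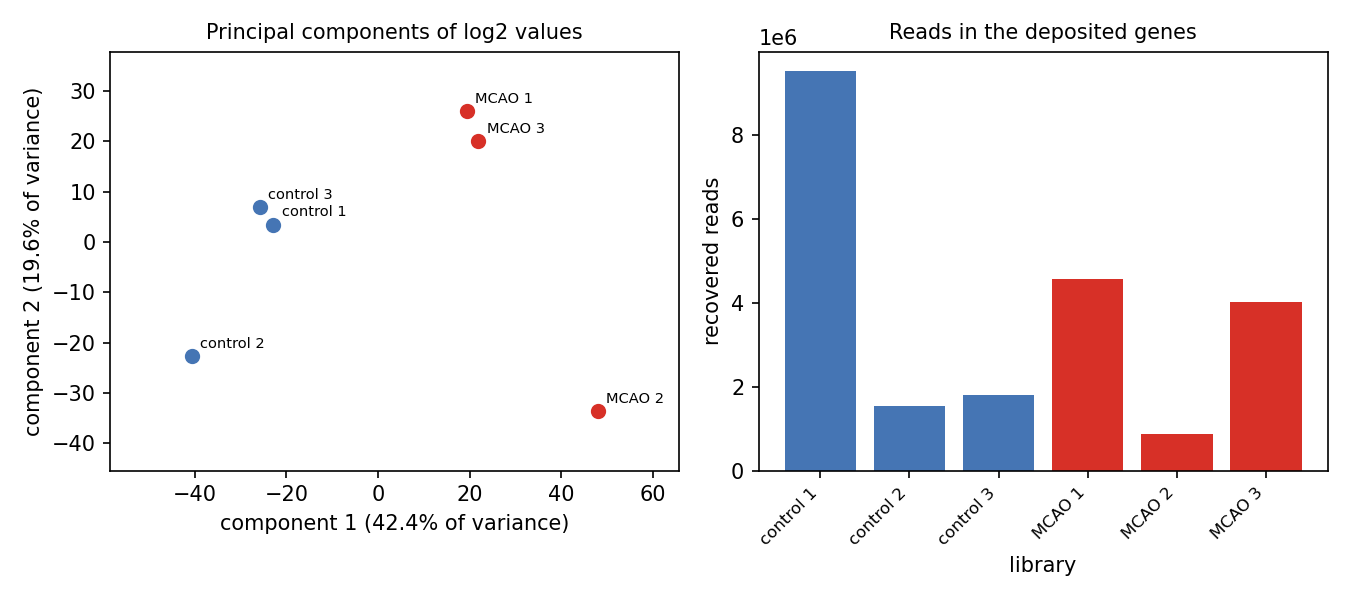
Left, the 6 libraries on the principal components of log2 scaled read counts (percent of variance on each axis, blue control, red MCAO); right, recovered reads per library, with bars from 0. Controls lie at -22.9 or below on the first component and MCAO libraries at 19.5 or above, and control 2 (1538901 reads) and MCAO 2 (882263 reads) lie lowest on the second.

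The astrocyte intermediate filament genes Gfap and Vim and the secreted phosphoprotein gene Spp1 were many-fold higher after MCAO. Gfap (chromosome 11, 102887336 to 102897200) went from 576 ± 64.9 scaled reads in controls to 6372 ± 1459.8 (SD, n = 3 each), a log2 change of 3.45 (SE 0.18, adjusted p = 1.93e-07). Vim (chromosome 2, 13574311 to 13582826) rose from 63.2 ± 6.43 to 1042 ± 480, by 3.93 (SE 0.24). Spp1 (chromosome 5, 104435111 to 104441053) rose from 29.7 ± 8.90 to 719 ± 304, by 4.49 (SE 0.29). The membrane serine protease gene St14 (chromosome 9, 31088590 to 31131811) rose by 3.84 (SE 0.31), the complement gene C1qb (chromosome 4, 136880126 to 136886200) by 3.49 (SE 0.26), and mt-Nd3, a mitochondrially encoded subunit of respiratory complex I, by 3.36 (SE 0.58, adjusted p = 0.00592). The controls differed widely in mt-Nd3, at 66.8, 10.6 and 7.55 scaled reads in controls 1, 2 and 3, against 271, 243 and 109 in MCAO 1, 2 and 3. Among called genes with a mean in the upper 50% of tested genes, those that fell most included Rgs9 (chromosome 11, 109225348 to 109298181), at -1.49 (SE 0.20), the dopamine receptor gene Drd1 (chromosome 13, 54051183 to 54055658), at -1.48 (SE 0.23), and the GABA-A receptor subunit gene Gabrb2 (chromosome 11, 42419515 to 42632591), at -1.46 (SE 0.27). The phosphodiesterase genes Pde10a (chromosome 17, 8525187 to 8986648; -1.39, SE 0.17) and Pde7b (chromosome 10, 20397052 to 20725078; -1.38, SE 0.22) fell too. Adjusted p of these 5 genes lay between 0.000376 and 0.00932. Drd1 went from 128 ± 17.3 to 45.7 ± 10.4 scaled reads, and Pde10a from 448 ± 76.8 to 169.5 ± 25.0.

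Of 12549 genes tested, 387 were called, 288 higher and 99 lower after MCAO. A log2 change of at least 1 in size was seen in 203 of the higher and 30 of the lower genes. The 3 MCAO libraries lay all above or all below the 3 controls in 386 of the called genes and in 24.9% of tested genes, where chance gives 10%. The median log2 change of all tested genes was -0.01. Never above the floor in controls were 7 of the tested genes, and 0 were so after MCAO. Leaving out 1 library gave 227 called genes without control 1, 306 without control 2, 245 without control 3, 271 without MCAO 1, 234 without MCAO 2 and 148 without MCAO 3. Higher genes numbered 174, 186 and 120 without MCAO 1, 2 and 3. Lower genes numbered 23, 25, 48 and 28 without control 1, control 3, MCAO 2 and MCAO 3, and genes changed by at least 1 in log2 numbered 128 without MCAO 3. Called genes numbered 157 with no intensity trend (mt-Nd3 adjusted p = 0.121 and Gabrb2 0.112), 0 by a test of each gene by itself without moderation (1389 at an unadjusted p under 0.05), and 1002 with library weights, an alternative chosen after seeing the data. With robust moderation mt-Nd3 was not called either (adjusted p = 0.161).

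**Figure D2:**
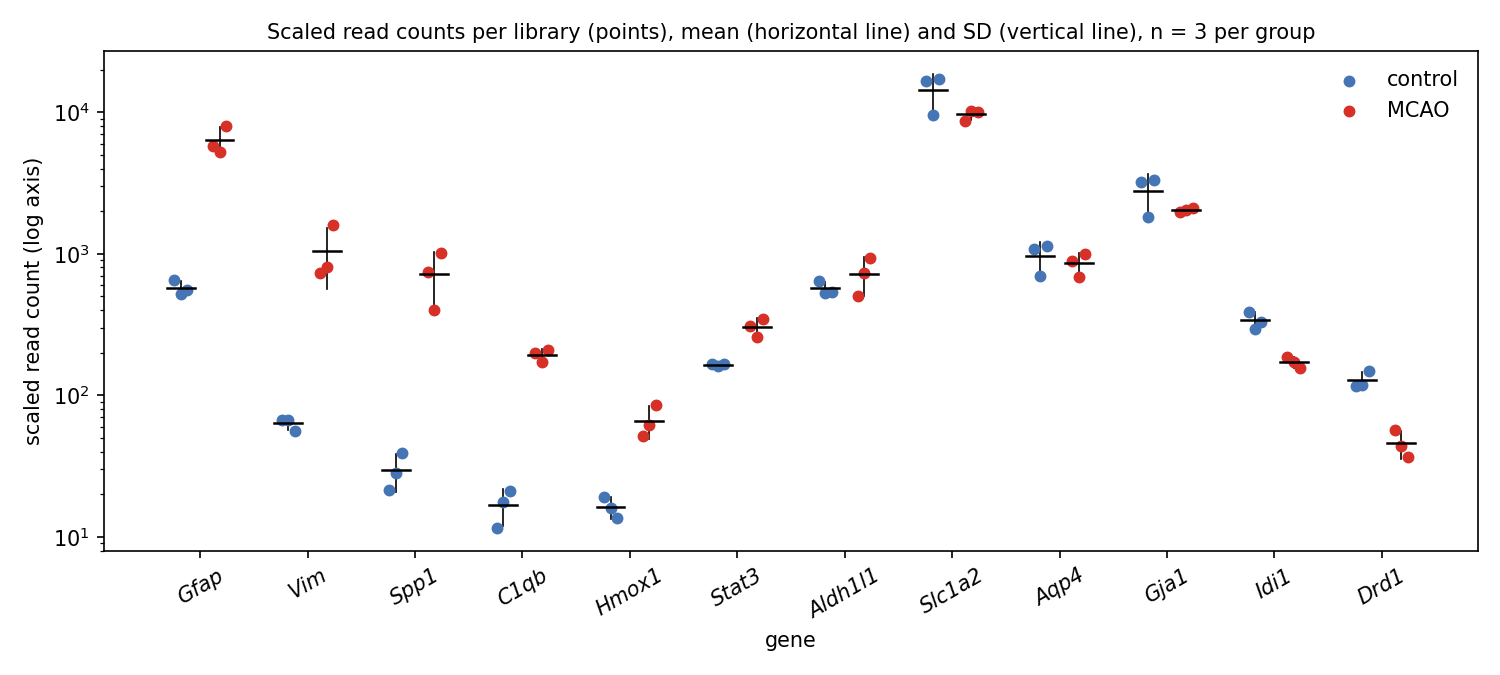
Scaled read counts (log axis) of 12 named genes in each library (points; blue control, red MCAO), with the mean (horizontal line) and SD (vertical line) of 3 animals per group. Gfap, Vim, Spp1, C1qb, Hmox1 and Stat3 lie higher in all 3 MCAO libraries and Idi1 and Drd1 lower, while for Slc1a2 and Gja1 control 2 lies apart from the other controls.

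Genes described for reactive astrocytes in general rose together. Of 11 measured pan-reactive genes 8 rose and 0 fell (9 rose when adjusted over the list alone), with a median log2 change of 2.89 (camera adjusted p = 4.55e-17; adjusted p = 0.0986 with an estimated correlation). Lcn2, which encodes the iron-carrier-binding protein lipocalin 2, was at the floor in every control and at 94.7 ± 25.5 scaled reads after MCAO. That mean was at least 26.5-fold higher against a floor of 3 reads per library averaged over the controls, and MCAO 2 was lowest at 65.3. Timp1, an inhibitor of matrix metalloproteinases, had 1 read in controls 2 and 3 together and 162 reads in the MCAO libraries, a ratio of 56.4 per unit of depth (95% exact interval 9.98 to 2241). Control 1 can hide up to 3 reads. Of 13 genes of the A2 list, first described after ischemia, 9 were measured. Of these 9 genes 6 rose and 0 fell, also when adjusted over the list alone (median 2.51, adjusted p = 8.19e-08; adjusted p = 0.0987 with an estimated correlation). Tgm1, a transglutaminase gene, was at the floor in every control and at 142 ± 64.8 after MCAO. That mean was at least 39.7-fold higher against the same floor, and MCAO 2 was lowest at 71.5. Cd14, a co-receptor for bacterial lipopolysaccharide, rose by 2.94 (SE 0.53). Of 13 genes of the A1 list, first described after systemic lipopolysaccharide, 9 were measured, and C3 was not among them. Of these 9 genes 2 rose and 0 fell, also when adjusted over the list alone (median 0.52, adjusted p = 0.0075; adjusted p = 0.0994 with an estimated correlation). These were the class I antigen gene H2-D1, at 1.13 (SE 0.15), and the immunoproteasome gene Psmb8, at 1.92 (SE 0.46). Both genes are also in the MHC class I list. The A2 minus A1 score lay higher in all 3 MCAO libraries, by 1.43 (SE 0.18) on the log2 scale and by 0.93 (SE 0.18) without the gene at the floor, with an exact permutation p of 0.1, the smallest that 3 against 3 animals allow. In the same libraries microglia markers had a median of 1.89 (13 of 18 risen) and the 2 measured of 18 blood myeloid markers a median of 2.47. The A1 list was not called among genes with a mean of at least 50 (adjusted p = 0.131). Psmb8 was not called with any 1 library but control 2 left out (adjusted p 0.0769 to 0.149), with quantile normalisation (0.0536) or with the gene span trend removed (0.0770), nor Cd14 without MCAO 1 or MCAO 3 (0.0617 and 0.0854).

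Markers of astrocytes in the resting brain did not rise with the reactive genes. Of 18 measured markers limma called 0 (0 higher and 2 lower when adjusted over the list alone, 4 at an unadjusted p under 0.05, 1 called by edgeR). Their median log2 change was -0.14 (camera adjusted p = 0.0797, and 0.697 with an estimated correlation). Aldh1l1, a folate enzyme gene used as a pan-astrocyte marker, was at 571 ± 63.0 scaled reads in controls and 724 ± 219 after MCAO. Sparcl1, the most abundant marker, was at 17832 ± 6593 and 9736 ± 874 (log2 change -0.80, SE 0.29, adjusted p = 0.151). Aldoc, the brain aldolase gene, was at 7255 ± 1179.8 and 8727 ± 2066. All 16 genes for glutamate uptake, potassium and water channels and gap junctions had negative log2 changes, with a median of -0.15, and limma called 0 of them (0 when adjusted over the list alone, 4 at an unadjusted p under 0.05, 0 by edgeR). As a list they were lower than other genes (camera adjusted p = 0.0075; adjusted p = 0.561 with an estimated correlation). The glutamate transporter gene Slc1a2 was at 14380.3 ± 4177 and 9679.6 ± 864 (log2 change -0.53, SE 0.25, adjusted p = 0.273). The gap junction gene Gja1 was at 2787 ± 849 and 2032 ± 79.5 (-0.40, SE 0.21), and the water channel gene Aqp4 at 967 ± 240 and 861 ± 159 (-0.15, SE 0.20). Control 2 was low in these genes, with 9567 scaled reads of Slc1a2 against 16528 and 17046 in the other controls. Without it Slc1a2 (-0.80, adjusted p = 0.0168), Sparcl1 (-1.15, 0.00178), Gja1 (-0.69, 0.0124) and the astrocyte marker list (lower, 2.05e-06) were called. The marker list was also called without MCAO 2 (0.0213) or MCAO 3 (0.0107), and the transport list was not called without control 1 (0.152), control 3 (0.132) or MCAO 1 (0.182). With both control 2 and MCAO 2 left out, chosen after seeing the data, Slc1a2 (-0.84), Sparcl1 (-1.19), Gja1 (-0.69) and the marker list (adjusted p = 2.95e-08) were called. Library weights gave the same 4 calls (adjusted p 0.0294, 0.00508, 0.0275 and 0.000152), and removal of the gene span trend gave that of the marker list (0.0232). These calls of the marker list used the preset correlation of 0.01, while its estimated correlation was 0.72, so its genes are not independent evidence.

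Microglia markers rose after MCAO. All 18 had positive log2 changes, 13 rose (17 when adjusted over the list alone) and 0 fell, with a median of 1.89 (camera adjusted p = 3.17e-27; adjusted p = 0.0513 with an estimated correlation). Cd68, a lysosomal membrane protein gene of phagocytes, rose by 3.86 (SE 0.47), and Tyrobp, an adaptor of myeloid receptors, by 3.70 (SE 0.52). Chosen after their values were seen, Csf1r went from 188 ± 47.4 to 505 ± 89.3 scaled reads and Cx3cr1 from 104 ± 3.37 to 251 ± 28.5, while P2ry12 (1.00, SE 0.36) and Tmem119 (0.65, SE 0.34) were not called. Spi1, which encodes the myeloid transcription factor PU.1, rose by 2.49 (SE 0.60, adjusted p = 0.0394). Only 2 of the 18 genes on the blood myeloid list were measured, and both rose, also when adjusted over the list alone. They were Lyz2, a lysozyme gene, at 2.42 (SE 0.28), and Csf3r, a granulocyte growth factor receptor gene, at 2.51 (SE 0.57). That list had a median of 2.47 (adjusted p = 0.000203; adjusted p = 0.0987 with an estimated correlation). With 2 genes tested, it cannot tell blood myeloid cells from the microglia whose markers rose in the same libraries. Of 14 lymphocyte markers 0 were among the genes tested. Spi1 was not called without control 2 or any 1 MCAO library (adjusted p 0.056 to 0.150), with no intensity trend (0.0747) or with a pseudocount of 0.1 (0.0556), nor Csf3r with any 1 library but control 2 left out (0.0548 to 0.121).

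Complement genes rose alongside these microglia markers. Of 18 listed genes 9 were measured, and C3 was not among them. Of these 9 genes 5 rose (7 when adjusted over the list alone) and 0 fell, with a median of 1.99 (adjusted p = 9.28e-11; adjusted p = 0.0513 with an estimated correlation). C1qb went from 16.8 ± 4.88 to 194 ± 20.0 scaled reads and the receptor gene C3ar1 rose by 3.59 (SE 0.53). The list shares C1qa, C1qb and C1qc with the microglia markers; without them its median was 1.13 (adjusted p = 0.000606). Only 8 of 24 listed cytokine and chemokine genes were measured. Of the 8, Spp1 rose (3 when adjusted over the list alone) and 0 fell, with a median of 0.32 (adjusted p = 0.0204; adjusted p = 0.410 with an estimated correlation). The most abundant member, Cx3cl1, was at 1286 ± 84.7 and 1163 ± 162. The interferon response list, with 13 of 21 genes measured, had 2 risen genes (3 when adjusted over the list alone) and 0 fallen, with a median of 0.59 (adjusted p = 0.000507; adjusted p = 0.0987 with an estimated correlation). These were the interferon-inducible GTPase genes Gbp3, at 2.08 (SE 0.43), and Irgm1, at 1.38 (SE 0.26). In the MHC class I list H2-D1 and Psmb8 rose among 15 genes (6 when adjusted over the list alone) and 0 fell, with a median of 0.54 (adjusted p = 1.21e-05; adjusted p = 0.111 with an estimated correlation). H2-D1 went from 179 ± 19.0 to 391 ± 29.8. Microglia markers, with a median of 1.89, moved with each of these lists. The cytokine list was not called without control 2 or MCAO 1 (adjusted p = 0.0975 in each case), among genes with a mean of at least 50 (0.0888) or on ranks (0.199). The interferon list was not called among genes with a mean of at least 50 (0.131). Irgm1 was not called without MCAO 1 (0.0541) or MCAO 3 (0.0805), nor Gbp3 without MCAO 2 (0.0848) or MCAO 3 (0.0647) or with no intensity trend (0.0659).

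**Figure D3:**
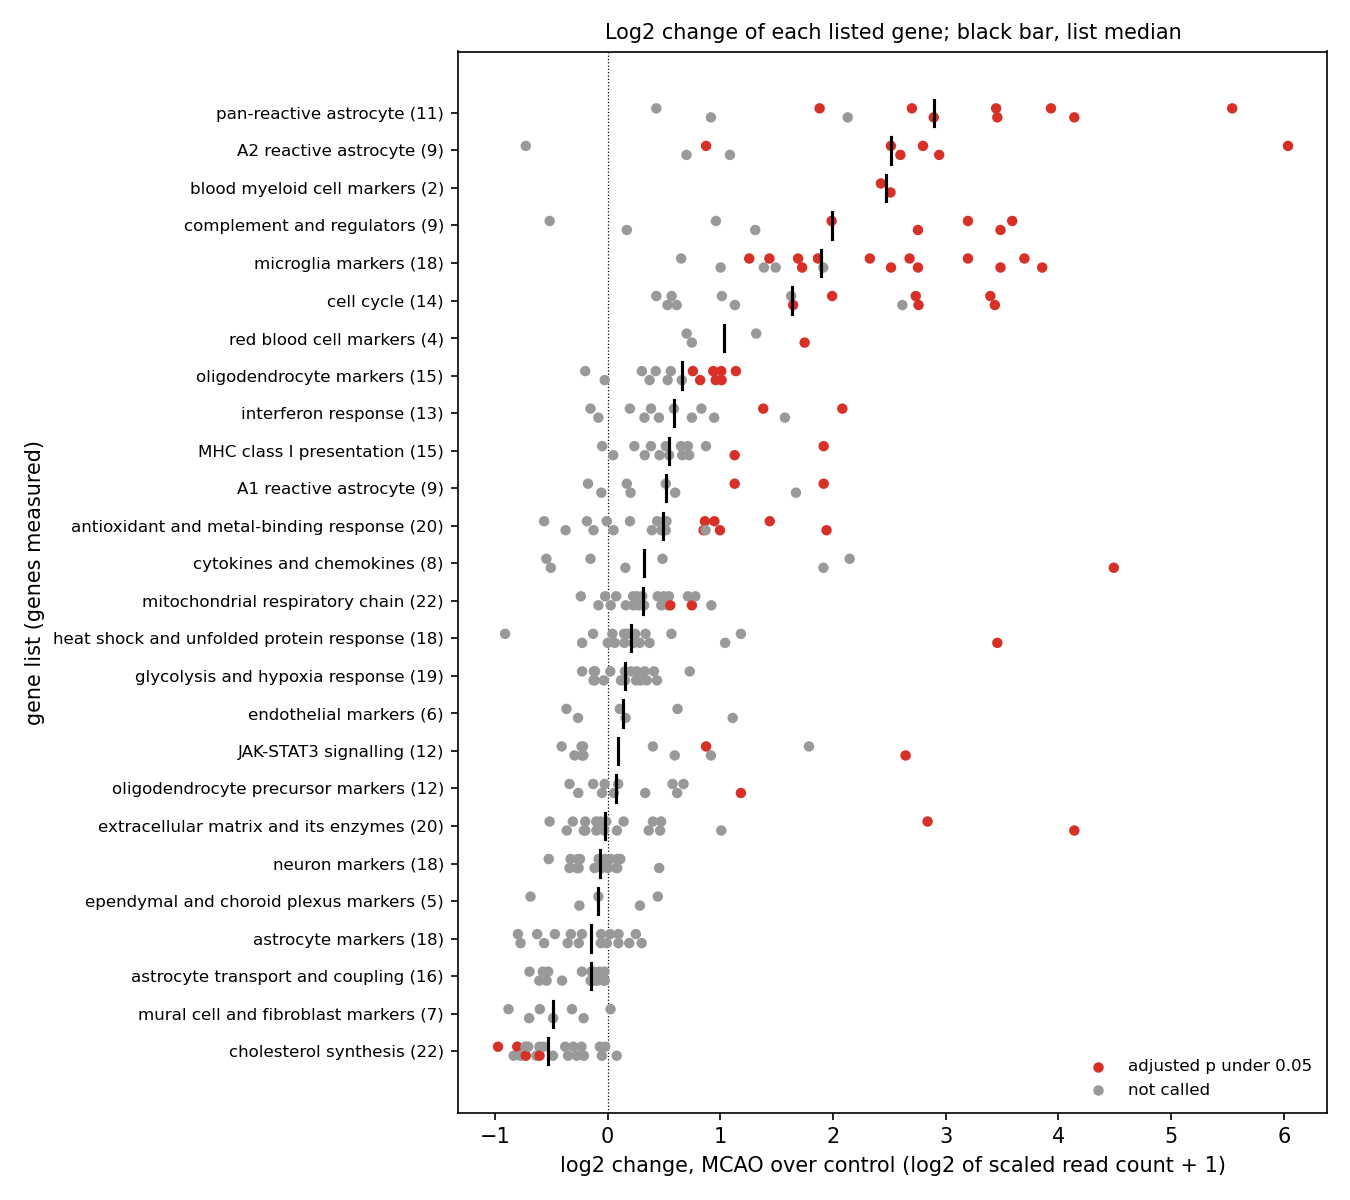
Log2 change (MCAO over control, of scaled read count + 1) of each measured gene in the 26 lists with a measured gene, with the number of genes in parentheses; red points were called, grey ones were not, and black bars are list medians. Medians run from 2.89 for pan-reactive astrocyte genes to -0.53 for cholesterol synthesis, with microglia markers at 1.89 and astrocyte and neuron markers at -0.14 and -0.07.

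Cell cycle genes had positive log2 changes in all 14 measured members of a list of 28. The other members were not tested, and some measured ones passed the filter only through their MCAO values. Cdk1, for example, had a control mean of 1.34 scaled reads. The 14 therefore do not stand for the whole list. Of the 14 measured genes 6 rose (10 when adjusted over the list alone) and 0 fell, with a median of 1.64 (adjusted p = 1.55e-10; adjusted p = 0.0513 with an estimated correlation). Cdk1, the mitotic kinase gene, was at the floor in controls 2 and 3, at 2.01 scaled reads in control 1 and at 26.2 ± 13.2 after MCAO. Its log2 change of 3.44 (SE 0.67) depends on the floor value and is no bound. Top2a, a topoisomerase gene of dividing cells, was at 1.15 and 14.2 in controls 1 and 2, at the floor in control 3 and at 42.2 ± 10.8 after MCAO (3.40, SE 0.69). Oligodendrocyte markers also rose: 7 of 15 (12 when adjusted over the list alone) and 0 fell, with a median of 0.66 (adjusted p = 4.11e-09; adjusted p = 0.0579 with an estimated correlation). Gjb1, a gap junction gene, rose by 1.14 (SE 0.29) and Fa2h, a myelin lipid hydroxylase gene, by 1.01 (SE 0.22). Of 12 oligodendrocyte precursor markers, Cspg4, the NG2 proteoglycan gene, rose by 1.18 (SE 0.30; 2 genes when adjusted over the list alone), 0 fell, and the list, with a median of 0.07, was not called (adjusted p = 0.158). Olig1 was at 421 ± 95.5 and 671 ± 147 (adjusted p = 0.0861). Microglia markers, with a median of 1.89, rose in the same libraries as the cell cycle and oligodendrocyte genes. Cdk1 was not called without MCAO 1 (0.0816) or MCAO 3 (0.129), or Top2a without MCAO 3 (0.105). Nor was Cspg4 called with any 1 library but MCAO 2 left out (0.0554 to 0.188), Fa2h without control 1, control 2, MCAO 1 or MCAO 2 (0.0509 to 0.0916), and Gjb1 with any 1 of the 6 left out (0.052 to 0.164). With no intensity trend Top2a (0.104), Fa2h (0.0799), Gjb1 (0.0968) and Cspg4 (0.183) were not called. Gjb1 was also lost with a pseudocount of 0.1 (0.0508), quantile normalisation (0.0618), the gene span trend removed (0.0747) or the 2 shallowest libraries left out (0.126), and Cspg4 among genes with a mean of at least 50 (0.0512). Olig1 was called without MCAO 1 (0.0441) and with library weights (0.0421).

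Cholesterol synthesis genes were lower after MCAO. Of 22 genes, 4 fell (10 when adjusted over the list alone) and 0 rose, with a median of -0.53 (adjusted p = 3.56e-08; adjusted p = 0.0986 with an estimated correlation). Idi1, an isomerase of the isoprenoid branch, went from 339 ± 46.1 to 171 ± 14.4 scaled reads (-0.97, SE 0.16, adjusted p = 0.00348) and Msmo1, a sterol oxidase gene, from 530 ± 118 to 299 ± 32.5 (-0.80, SE 0.18, adjusted p = 0.0272). In the same libraries the astrocyte transport list was lower, with a median of -0.15, and microglia and oligodendrocyte markers were higher, with medians of 1.89 and 0.66. Markers of striatal projection neurons, a list chosen after seeing the data, had a median of -0.95. Sp1, which encodes a general transcription factor, fell from 102 ± 4.34 to 52.9 ± 3.75 (-0.93, SE 0.20, adjusted p = 0.0237). Msmo1 was not called without control 1, control 3, MCAO 1 or MCAO 3 (adjusted p 0.0582 to 0.115), nor Sp1 without control 1, control 3, MCAO 2 or MCAO 3 (0.0523 to 0.105). With no intensity trend Idi1 (0.0558) and Msmo1 (0.170) were not called.

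Antioxidant and metal-binding genes rose, 6 of 20 with 0 fallen (13 risen and 1 fallen when adjusted over the list alone), with a median of 0.49 (adjusted p = 2.76e-06; adjusted p = 0.111 with an estimated correlation). Hmox1, a heme-degrading enzyme gene, went from 16.3 ± 2.86 to 66.2 ± 17.4 scaled reads (1.94, SE 0.31) and the glutathione peroxidase gene Gpx1 from 81.9 ± 6.82 to 224 ± 26.8 (1.44, SE 0.17). Nuclear-encoded respiratory chain genes had a median of 0.32 (adjusted p = 4.29e-06; adjusted p = 0.111 with an estimated correlation), with 2 of 22 risen (9 when adjusted over the list alone) and 0 fallen. The risen genes were the cytochrome oxidase genes Cox6a1, at 0.75 (SE 0.17), and Cox5a, at 0.56 (SE 0.14). In the heat shock and unfolded protein list Hspb1, a small heat shock protein gene, rose by 3.46 (SE 0.54) among 18 genes (3 when adjusted over the list alone) and 0 fell, with a median of 0.20 (adjusted p = 0.0204; adjusted p = 0.111 with an estimated correlation). Hsp90aa1 was at 2761 ± 658 and 3016 ± 362. Of 19 glycolysis and hypoxia genes limma called 0 (0 when adjusted over the list alone, 2 at an unadjusted p under 0.05, 0 by edgeR), with a median of 0.15 (adjusted p = 0.0806). Aldoa was at 4592 ± 321 and 5105 ± 259.9, and Pkm at 4337 ± 1075 and 4753 ± 542. Microglia markers, with a median of 1.89, rose along with the antioxidant, respiratory chain and heat shock lists. The heat shock list was not called without control 3 (0.108) or MCAO 3 (0.0680), among genes with a mean of at least 50 (0.0513) or with the gene span trend removed (0.234). Glycolysis was called without control 2 (0.00488) or MCAO 1 (0.0360), on ranks (0.0459), with library weights (0.00432) and without the 2 shallowest libraries (0.00277). Cox5a was not called with any 1 of the 6 libraries left out (0.0533 to 0.164), nor Cox6a1 without control 2 or any 1 MCAO library (0.0582 to 0.103). Cox5a and Cox6a1 were also lost with no intensity trend (0.174 and 0.176) and with the gene span trend removed (0.0787 and 0.0866), Cox5a with a pseudocount of 0.1 (0.0522), and Cox6a1 without the 2 shallowest libraries (0.0539).

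In JAK-STAT3 signalling the transcription factor gene Stat3 rose from 165 ± 3.28 to 305 ± 44.7 scaled reads (0.87, SE 0.16, adjusted p = 0.00778) and its feedback inhibitor gene Socs3 by 2.64 (SE 0.57, adjusted p = 0.0239). These 2 of 12 genes rose (3 when adjusted over the list alone) and 0 fell, and the list, with a median of 0.09, was not called (adjusted p = 0.255). In the extracellular matrix list the fibronectin gene Fn1, at 2.84 (SE 0.40), and Timp1 rose among 20 genes (2 when adjusted over the list alone) and 0 fell. Its median was -0.02, its mean 0.39 and its test pointed up without a call (adjusted p = 0.348). Microglia markers, with a median of 1.89, rose along with these 4 genes. Stat3 was not called without MCAO 3 (0.0647), nor Socs3 without control 3 or any 1 MCAO library (0.0536 to 0.0935), and neither was called with no intensity trend (0.0759 and 0.0654). The JAK-STAT3 list was called without MCAO 2 (0.0334) and without the 2 shallowest libraries (0.0278).

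Neuron markers were abundant in every library and limma called 0 of 18 (0 when adjusted over the list alone, 3 at an unadjusted p under 0.05, 0 by edgeR), with a median of -0.07 (adjusted p = 0.217). Camk2a was at 8422 ± 387 scaled reads in controls and 7157 ± 1136.7 after MCAO, and Snap25 at 3422 ± 51.9 and 3664 ± 632. Markers of vascular and ventricular cells were few and had 0 calls by limma and 0 by edgeR, and 0 when adjusted over the list alone. The 6 endothelial genes, 0 of them at an unadjusted p under 0.05, had a median of 0.13 (adjusted p = 0.550), with Itm2a at 23.2 ± 15.3 and 32.2 ± 3.97 and Flt1 at 27.3 ± 3.56 and 21.6 ± 6.80. The 7 mural cell and fibroblast genes, 1 at an unadjusted p under 0.05, had a median of -0.48 (adjusted p = 0.0610), with Vtn at 149 ± 19.1 and 121 ± 33.0 and Pdgfrb at 108 ± 26.9 and 70.0 ± 11.9. The 5 ependymal and choroid plexus genes, 2 at an unadjusted p under 0.05, had a median of -0.08 (adjusted p = 0.891), with Ttr at 511 ± 35.5 and 707 ± 158 and Clic6 at 172 ± 39.6 and 146 ± 44.6. Of 4 globin genes Hba-a1 rose by 1.75 (SE 0.34; 2 genes when adjusted over the list alone) and 0 fell, with a list median of 1.03 (adjusted p = 0.00213; adjusted p = 0.0987 with an estimated correlation). Its near-identical partner Hba-a2 was at 133 ± 44.0 and 212 ± 43.2. Hba-a1 was not called without MCAO 2 (0.0574) or with no intensity trend (0.113), and Hba-a2 was called without control 2 (0.0266), with library weights (0.00925) and without the 2 shallowest libraries (0.0170). The mural list was called as lower without control 2 (0.0222) or MCAO 1 (0.00888), with no filter (0.0240), quantile normalisation (0.0489), on ranks (0.0390) and with the gene span trend removed (0.0310).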

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

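The settings with library weights, without the 2 shallowest libraries, with the gene span trend removed and with lists of fewer than 3 measured genes left out were chosen after seeing the data. Against 387 called genes (288 higher, 99 lower, 233 changed by at least 1 in log2), no intensity trend gave 157 (139, 18 and 151) and an adjusted p under 0.01 gave 134 (116, 18 and 118). Without moderation a Welch test of each gene called 0 in each class, with 1389 at an unadjusted p under 0.05; in the simulation it recovered 4% of 8-fold changes. Among genes with a mean of at least 50 there were 272, of which 181 were higher and 120 changed by at least 1. Library weights gave 1002 (566 higher, 436 lower), and leaving out control 2 and MCAO 2 gave 567 (236 lower). With 1 library left out the counts were 148 to 306 called, 120 to 220 higher, 23 to 97 lower and 128 to 205 changed by at least 1, and 15 to 19 lists were called. The cause of these differences was not tested, apart from fewer samples or genes and a stricter threshold by construction. The other settings (pseudocounts, no filter, scaling, robust moderation, edgeR and the span trend) gave 295 to 520 called genes; edgeR called 384 of the 387. No called gene changed sign while tested in any setting. Camera called 17 lists with the preset correlation and 0 with an estimated one (lowest adjusted p = 0.0513, 11 at an unadjusted p under 0.05, 15 by fry); with lists of fewer than 3 measured genes left out, 16 and 3. The first component held 50.4% of the variance over the 500 most variable genes, against 42.4%. Of the 66 named genes 43 were called, and 22 stayed called in every setting but no moderation and an adjusted p under 0.01. Over all named genes and settings 1137 calls were the same, 149 were lost and 15 gained; over lists 481, 43 and 19; of list medians 396 were within 1 SD and 45 moved further. No paired analysis was possible because the labels give no shared replicate numbers. Depth limits low genes most in MCAO 2, where 3 reads equal 9.33 scaled reads, and the median SE of 0.23 limits small changes: 14% of simulated 1.5-fold changes were recovered.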

Other observations

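The striatal, cortical, lysosomal and second microglia lists, the choice of 3 gene families out of 23 looked through, and both microglia tests came after the data had been seen; genes named in this part were chosen after their values were seen. No test is given for the striatal and lysosomal lists and the 3 families, which were picked because of their values; the second microglia list was written after the rise of the first was seen. Markers of striatal projection neurons were lower after MCAO: 9 of 15 fell and 0 rose, with a median log2 change of -0.95. Rgs9, Drd1 and Pde10a, which helped prompt the list, are among the 9. The others include the dopamine receptor gene Drd2, from 66.7 ± 7.18 to 16.3 ± 3.74 scaled reads (SD, n = 3 each; -1.99, SE 0.30), and the adenosine receptor gene Adora2a, from 128 ± 27.7 to 37.2 ± 11.5 (-1.79, SE 0.27). Neuropeptide genes of the same cells were not called: Penk was at 348 ± 14.1 and 291 ± 127, and Pdyn at 125 ± 7.08 and 147 ± 49.0. Of 12 markers of cortical excitatory neurons limma called 0 (1 at an unadjusted p under 0.05, 0 by edgeR), with a median of -0.02. The striatal minus cortical score was lower in all 3 MCAO libraries, by -0.97 (SE 0.13), on a list that holds genes that prompted it.

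Lysosomal protease and glycosidase genes rose: 14 of 21, with 0 fallen and a median of 0.94. Ctsd, the cathepsin D gene, went from 1456 ± 112 to 4292 ± 692 (1.55, SE 0.17) and Ctsb, the cathepsin B gene, from 2078 ± 381 to 3731 ± 549 (0.85, SE 0.18), while Gaa, a glycogen-degrading enzyme gene, was at 2048 ± 123 and 1888 ± 296. The list shares 2 genes, Ctss among them, with the microglia markers, which rose with it. Of 21 gamma protocadherin genes, which encode adhesion molecules and share constant exons so that their counting is uncertain, Pcdhga3 (-2.02, SE 0.35) and Pcdhgc5 (-0.82, SE 0.20) fell and 0 rose, with a family median of -0.96. Pcdhga8, by far its most abundant member, was at 1657 ± 191 and 1790.3 ± 149.9 (0.11, SE 0.15) and was not called.

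Microglia markers rose in precipitates meant to hold RNA of tagged cells. A lower astrocyte share alone would raise all other cell types alike, yet the microglia mean exceeded the neuron mean by 2.25 (SE 0.098). Precursor markers, far less abundant than neuron markers, had a mean of 0.23 (SE 0.09), oligodendrocyte markers 0.62 (SE 0.06) and globin genes 1.13 (SE 0.36). These unlike means argue against a lower share as the only cause. Striatal neuron markers fell (median -0.95), so neurons may be no fixed reference, and a lower share as part of the cause stays open. More microglial RNA in the MCAO precipitates may account for the rise. All 25 further microglia genes, sharing none with the first list, had positive changes, with 14 called. Their median was 1.49 (SE of the mean 0.13), above the bound of 0.94 set for that test. Because this second list was written after the first had risen, its rise is not independent support, and no p-value is given. It cannot tell apart the sources left open below. Of the abundant markers, Csf1r and Cx3cr1 reached 505 and 251 scaled reads, against 3664 for the neuron gene Snap25, and some genes of such lists are expressed in other cells too. Whether that RNA came from more or activated microglia bound without the tag, or from tagged cells expressing these genes, stays open, since input RNA was not used here.

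Mitochondrially encoded transcripts, which are not translated by tagged cytosolic ribosomes, rose: 12 of 15, with a median of 1.505, and their share of reads went from 0.753% to 0.896% in controls to 2.57%, 2.54% and 1.27% in MCAO 1, 2 and 3. Apart from mt-Nd3, at 3.36 with uneven controls, their log2 changes ran from 0.96 (mt-Co1) to 1.74 (mt-Rnr1). Nuclear-retained RNAs had a median of 0.15 (SE of the mean 0.25), under the bound of 0.75 set for more background RNA of every kind. Of these 9 RNAs limma called 0 (3 at an unadjusted p under 0.05, 1 by edgeR), with log2 changes from -0.85 (Snhg14) to 1.26 (Neat1). That argues against background that includes nuclear RNA as the whole cause. Malat1 was at only 51.0 ± 2.51 and 57.4 ± 12.2 scaled reads, and a rise of cytoplasmic background alone was not tested, since the list holds nuclear RNAs. Under median ratio and quantile scaling the mitochondrial median stayed at 1.48 or more, above the bound of 0.75 set for scaling between libraries. Median ratio scaling hardly moved the deposited values, with an all-gene median of -0.01 before and after it. Both scalings rest on the bulk of genes, so they show only that the rise did not hang on the choice among such scalings. Mitochondria carried along with the precipitate and a change in the tissue after MCAO were not tested and stay open.

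Ribosomal protein genes all had positive changes: 23 of 81 rose and 0 fell, with a median of 0.56. Log2 change fell with gene span across genes, which are not independent replicates (Spearman rho -0.36; -0.07 with the trend removed), and the median span was 9.76 kb for higher and 54.4 kb for lower genes, against 24.9 kb for all. With that trend removed the ribosomal protein median was 0.34 (SE of the mean 0.11), and without MCAO 2, the shallowest library, 0.45 (SE 0.14); it was 0.47 without control 2 and 0.36 without both. The first 2 medians moved toward the bound of 0.28 set for their tests and neither is clear of it by 2 SE, so a part played by gene length or by the shallow libraries cannot be told apart from a change after MCAO.

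Of the 10 splits of the 6 libraries into 3 and 3, only the real one, 1 of 10, called as many as 387 genes. The highest of the other 9 by limma was 0 (513 at an unadjusted p under 0.05, 0 by edgeR), and 10 splits are too few for a share under 0.05. Each of the other 9 mixes control and MCAO libraries within its groups, so a real difference widens the spread there and lowers the calls. Their 0 calls are therefore no level of chance calls to set against 387.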
